A study of Mus musculus with 7 samples.

How the data were processed

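Single cells were profiled with droplet-based 3′ RNA-seq (10x Genomics chemistry) in 7 mouse samples, each in a group of its own, and sequenced with a target of about 50000 reads per cell, per the labels' protocols. Before loading, cells were sorted by flow cytometry with a dye that marks dead cells, and the feeder cells had been stained with the same dye, per the labels' protocols. The deposited values are whole-number counts of unique molecular identifiers (UMIs), each standing for 1 captured transcript, per gene and cell barcode. They were made with Cell Ranger 3.1.0 on the mm10 build, per the submitters' processing notes, which also name R 3.6.1 and Seurat 3.1.1 without a role. The deposited barcodes, gene symbols and Ensembl identifiers carry no measurement. The annotation release, the merging step and whether depth was equalised between libraries are not given in the sources used here.

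All cells stood in 1 matrix of 31053 genes and 64712 barcodes, and each barcode ended in a suffix number from 1 to 7. No label tied a suffix to a sample. The libraries are therefore named by suffix (library 1 to library 7), and none was assigned to a genotype, cell source or treatment from its values or from the order of the labels. Comparisons between knockout and wild type, between 2i and no 2i, and between stages were not made. Cry1 was not used to assign libraries. Each library's value is given, or the range and median over the libraries, with no test. The matrix was pooled, so all values that join libraries are descriptions of 1 pool. Ensembl identifiers were matched to GENCODE release M21 on the same build, which held 31011 of the 31053 (99.9%), and coordinates are from it.

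Cells were kept with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs. Doublets were scored in each library with a Scrublet-style simulation of 2 doublets per cell and an automatic threshold. It marked 33 cells, 0.0116% to 0.109% per library, so the caller did not work and doublets stand largely unremoved. Of the 64712 barcodes 58816 were kept (90.9%), from 86.1% in library 5 to 95.0% in library 3. Of all barcodes 5612 failed on mitochondrial share, 4583 on genes and 2193 on UMIs, and many failed more than 1 of these filters. Cells were scaled to 10000 counts and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 gave 17 clusters, without batch integration. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and leidenalg 0.10.2.

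The 16 lists of cell type markers, the 22 other gene lists and the rule for named genes were written before the data were examined. By that rule Cry1 comes first, then, per list, up to 4 members with the largest absolute log2 ratio and up to 2 with the highest level, among members reaching 5 CPM (UMI counts scaled to a library or class total). Over unassigned libraries the ratio used was that of the highest to the lowest library, a reading of the rule chosen after the data were seen. Cry2, Per2, Dbp, Nfil3, Hbb-y, the marker genes given with values and the genes drawn in the plots were chosen after their values were seen. The thresholds for naming a cluster were also set after the data were seen: at least 4 markers of a list at 50 CPM or more and at 2 or more times the level of all other cells. A looser look, which would have named more clusters, came first. A cluster was also left unnamed if lists tied for most markers. The same was done if its cells were far shallower than their libraries and no marker of its list was among its leading genes. The fibroblast and smooth muscle or myofibroblast lists were joined, and cluster 8 was left unnamed because Sbsn and Krtdap, genes of cornifying skin, were 2 of its 10 leading genes. It had 7 fibroblast markers raised, 1 of them (Dcn) also among the leading genes, and 0 markers of any other list. Both choices followed the data.

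Per library and per class, UMI counts were summed and divided by the total to give CPM. Exact Poisson intervals for sums and exact (Clopper-Pearson) binomial intervals for shares are at the 95% level and cover counting error only. A share of 0 is given with the limit that 3 counts allow. The planned comparison of pluripotent-like with fibroblast-like cells was to be made within libraries holding at least 50 cells of both classes. 0 libraries did, so counts summed over all libraries, an alternative listed before the data were seen, are given as the main value. Log2 ratios used a pseudocount of 1 CPM and genes at 5 CPM or more in either class, and class markers were left out of the lists. A list's median was set among 10000 random lists matched on mean expression in 20 bins, and its interval came from 1000 Poisson draws. Shares of cells with a UMI were computed after thinning each cell to 5000 UMIs, with shallower cells left out. The clock, S phase, G2 and M phase, and p53 lists were chosen as the main lists, and the 15 genes for shares of cells with a UMI were picked, after the data were seen.

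The ratio step was tested on simulated counts for the pluripotent-like against fibroblast-like comparison, on 9436 genes with 200 changed. Genes changed by 1 log2 unit came back at a median of 0.95 and −0.97, those changed by 2 units at 1.94 and −1.87, and 0 unchanged genes came back beyond 1 unit. Both classes were drawn as Poisson counts from the fibroblast-like mean at the real totals, without variation between cells or libraries. At such totals unchanged genes could hardly differ, so the ratio run checks the calculation only and gives no error rate for the real ratios. Clustering and naming were run on 4000 simulated cells over 31053 genes with a pluripotent-like share of 5%, which came back as 5% with 0 cells called wrongly. That share was far above the 0.314% and 0.287% seen in libraries 5 and 7. The run therefore cannot tell whether shares that low are recovered. It also does not bear on the 47.6% of the pool in clusters left unnamed, so no error rate for the real cells is drawn from it. Alternatives covered the cell filter, doublets, clustering settings, the scale, the pseudocount, the filter on low genes, thinning depth, each library left out and, chosen after the data were seen, cluster 8 counted as fibroblast-like.

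Total UMIs of kept cells ran from 178566291 in library 7 to 323831795 in library 1, so that 3 UMIs stood for 0.0168 and 0.00926 CPM.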

Results

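Single-cell transcriptomes were collected from 7 mouse samples in a study of the clock gene Cry1 during reprogramming to induced pluripotent stem cells (iPSCs). The labels describe embryonic fibroblasts (MEFs) of wild-type and Cry1 knockout mice, wild-type iPSCs as a reference, and reprogrammed cells of both genotypes with and without 2i, a pair of kinase inhibitors used to culture naive pluripotent cells. The reprogrammed cells carried the 4 Yamanaka factors, were moved to feeder cells at day 4 and to stem cell medium at day 5, and the treated ones received 2i at day 9. Each of the 7 groups held 1 sample, so no value has a replicate check. Cell barcodes carried only a suffix number from 1 to 7, which no label ties to a sample, and the libraries are named by that number and belong to no group here. The kept cells numbered 11862, 7552, 7870, 7172, 8597, 8087 and 7676 in libraries 1 to 7. Their median depth ran from 20828.5 UMIs (library 7) to 25363.5 UMIs (library 1), and a median of 4410 to 4923 genes was seen per cell.

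Cry1, the targeted gene and a transcriptional repressor of the circadian clock, was detected in all 7 libraries. The gene (ENSMUSG00000020038) lies on the minus strand of chromosome 10, 85131700 to 85185064, in mm10. Its level was 15.04 CPM in library 1 (95% counting interval 14.6 to 15.5), 6.02 in library 2 (5.69 to 6.37), 15.4 in library 3 (14.8 to 15.9) and 6.95 in library 4 (6.59 to 7.33). It was 8.11 in library 5 (7.73 to 8.50), 11.2 in library 6 (10.7 to 11.7) and 14.6 in library 7 (14.01 to 15.1). The range was 2.55-fold with a median of 11.2 CPM. The intervals of libraries 1, 3 and 7 overlapped. The labels do not describe the knockout allele, and a 3′ tag outside a deleted part does not report the deletion, so these values check no label. Scaled without mitochondrial and ribosomal protein genes, library 1 in place of library 3 had the highest value, while library 2 had the lowest on all 4 scales run.

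Other clock genes did not follow the order of Cry1 over the libraries. Cry2, its paralog, ran from 5.31 CPM in library 1 to 16.5 in library 6, and Per2, a period gene that pairs with the cryptochromes, from 0.0525 in library 1 to 4.61 in library 7. The output gene Dbp ran from 10.2 (library 1) to 36.3 CPM (library 7), and the repressor Nfil3 from 4.23 (library 1) to 28.2 CPM (library 3). Rora, a nuclear receptor that activates Arntl, was at 0.926 CPM in library 1 and 28.9 in library 4, and Bhlhe40 was at 4.00 and 54.6 CPM in the same libraries. Of the 18 clock genes that reached 5 CPM, 14 were lowest in library 1, and Csnk1e, a kinase of the period proteins, was the most abundant, at 50.3 CPM in library 1 to 94.3 in library 4.

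**Figure D1:**
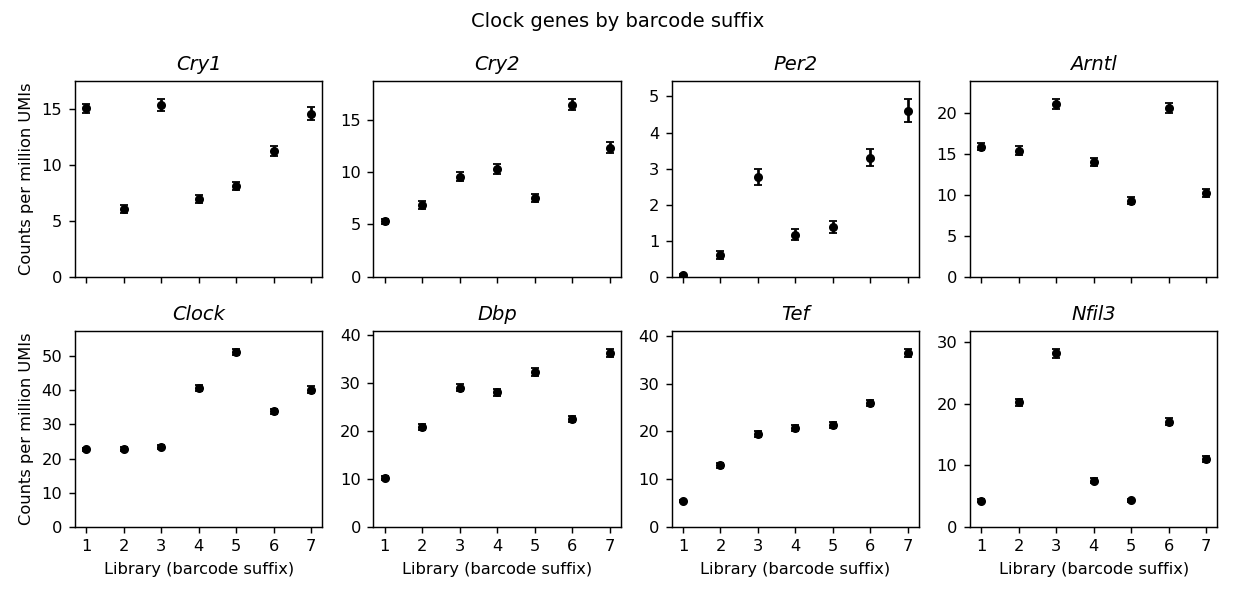
Level of 8 clock genes (y axis, CPM) in each library (x axis, barcode suffix). Points are sums over kept cells of 1 library and bars are 95% Poisson intervals, which cover counting error only; Cry1 ran from 6.02 to 15.4 CPM, and suffixes are not tied to samples.

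Clustering gave 4 named classes of cells, in suspensions that had been sorted with a dead-cell dye also used to stain the feeder cells, which can set shares. Pluripotent-like cells had 14 of the 15 pluripotency markers raised in both of their clusters. The germline and stem cell gene Dppa5a led cluster 1 (11281 cells), and H2-Eb1 and Calcoco2 led cluster 12 (630 cells). They numbered 11911 (20.3% of the pool, 19.9 to 20.6) and made up 100% of library 1, 0.314% of library 5 (27 cells, 0.207 to 0.457) and 0.287% of library 7 (22 cells, 0.180 to 0.434). In libraries 2, 3, 4 and 6 there were 0, which allows shares up to 0.0397%, 0.0381%, 0.0418% and 0.0371%. Without library 1 the pooled share was 0.104%. Fibroblast- or myofibroblast-like cells, in clusters marked by collagens such as Col1a2, by contractile genes such as Acta2 or by both, made up 31.8% of the pool (31.4 to 32.2). Their share was 98.4% in library 2 and in library 3, 5.88% in library 4, 0.907% in library 5, 21.0% in library 6 and 17.2% in library 7, and 0 cells were seen in library 1, which allows up to 0.0253%. Cluster 8 had 7 fibroblast markers raised, Dcn among its leading genes, and 0 markers of any other list, and was left unnamed for Sbsn and Krtdap by a choice made after the data were seen. With it counted, the shares were 58.1% in library 6 (57.0 to 59.2), 11.9% in library 4 (11.2 to 12.7), 0.977% in library 5 and 17.4% in library 7. Different clusters held them: clusters 3, 6 and 7 in libraries 2 and 3, and cluster 10, led by Gpx3 and Lgr5, with 1141 of the 1319 such cells of library 7. Cluster 11, led by Acta1 and Cnn1 and weighed below as cell fragments, held 89 of 422 such cells in library 4 and 19 of 78 in library 5. It held 254 of 1695 in library 6 and 134 of 1319 in library 7. With the stricter cell filter the cluster led by these genes was left unnamed. Cluster 10 had no contractile marker raised, and clusters 7 and 11 had no collagen raised. A cluster found mostly in 1 library may stand for that library and not for a cell type.

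Small numbers of other cells were found. Macrophage-like cells, with all 11 macrophage markers raised and Lyz2 and C1qb leading, numbered 118, of which 83 were in library 2, 34 in library 3 and 1 in library 6. Without library 2 their pooled share of 0.201% was 0.0683%. Glia- or neural crest-like cells, with Sox10, Foxd3, Erbb3 and S100b raised, numbered 113, of which 76 were in library 3 and 30 in library 2. Without library 3 their pooled share of 0.192% was 0.0726%. No cluster was named for the epithelial, keratinocyte, trophoblast, primitive endoderm, endothelial, neural, skeletal muscle, chondrocyte, adipocyte, germ cell or erythroid lists.

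The remaining 47.6% of the pool (47.2 to 48.0) was left unnamed: 94.1% of library 4, 98.8% of library 5, 79.0% of library 6 and 82.5% of library 7, against 0.119% and 0.191% of libraries 2 and 3. With cluster 8 counted as fibroblast-like, the unnamed share of library 6 was 41.9% (40.8 to 43.0). Cluster 2 (10226 cells) was led by Pdzrn4 and Klk1, with the epithelial genes Epcam and Krt8 raised, and lay in libraries 5 (6193 cells) and 7 (3860 cells). Cluster 4 (7222 cells) was led by Cemip and Nccrp1, with Msln, a mesothelial surface protein, and had 4539 cells in library 4 and 2508 in library 6. The list with most markers raised in it was neural, by Nes and Stmn2, fewer than the 4 required for a name. Cluster 5 (5350 cells) had Krt8, Epcam and the cycling genes Mki67 and Pbk among its leading genes and 3 keratinocyte markers raised, Sfn, Perp and Lgals7, fewer than the 4 required. Its cells numbered 1642, 1911, 609 and 1187 in libraries 4, 5, 6 and 7. Cluster 8 (3455 cells, 5.87% of the pool) was led by Sbsn and Emilin2, followed by Krtdap, and had 432, 6, 3003 and 14 cells in libraries 4, 5, 6 and 7. At Leiden resolution 1.0, 9156 cells in 3 clusters were keratinocyte-like and the unnamed share was 32.0%.

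**Figure D2:**
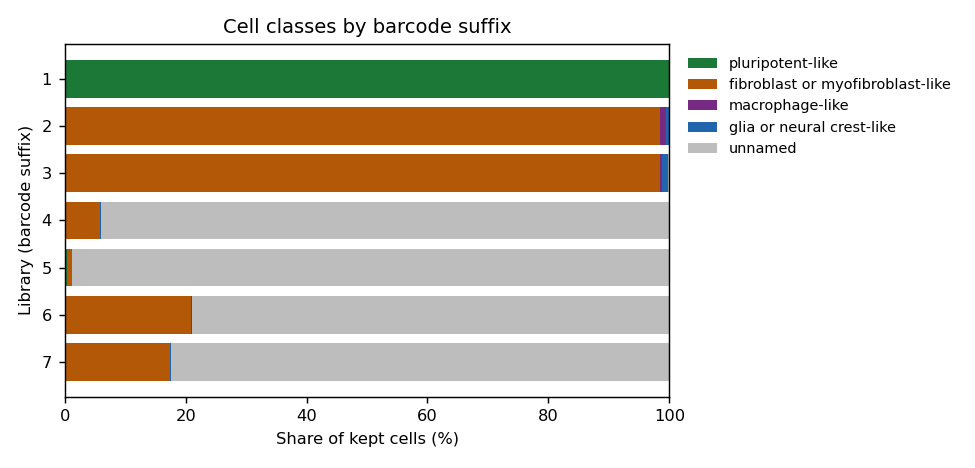
Share of kept cells (x axis, %) in each class for each library (y axis, barcode suffix), as stacked bars. Library 1 was 100% pluripotent-like, libraries 2 and 3 were each 98.4% fibroblast- or myofibroblast-like, and most cells of libraries 4 to 7 were unnamed, in library 6 only while cluster 8 is (41.9% unnamed with it counted as fibroblast-like).

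Mesenchymal and pluripotency genes covered wide ranges over the libraries. Vim, an intermediate filament of mesenchymal cells, was at 140 CPM in library 1, 1659 in library 5 and 4088 to 5401 CPM in the other five. Snai2, a repressor of epithelial genes, ran from 0.559 CPM (library 1) over 3.64 (library 5) to 80.7 (library 3), and all but 1 of the 10 members of that list were lowest in library 1. Of the reprogramming factors, Pou5f1 was at 349.7 CPM in library 1, 23.2 in library 5, 12.9 in library 7, 5.96 in library 4, 2.36 in library 6, and 0.544 and 0.603 in libraries 2 and 3. Sox2 was at 385, 23.5, 19.3, 11.4, 4.11, 0.903 and 0.877 CPM in the same libraries. Klf4 and Myc, which fibroblasts also express, ran from 25.0 to 259 and from 5.66 to 31.8 CPM. Whether transcripts of the introduced factors are counted by the 3′ tags is not given in the sources used here. Epcam, an epithelial adhesion protein, was at 0.215 and 0.145 CPM in libraries 2 and 3, 7.84 in library 6, 44.2 in library 4, 79.2 in library 7, 101 in library 1 and 201 in library 5. The primed list was led by Fst, a binding protein of activin, at 26.2 CPM (library 1) to 274 (library 6). Of the two-cell-like list 0 members reached 5 CPM.

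Signalling target genes also differed between libraries. Sp5, a direct target of β-catenin, was at 19.5, 18.4 and 14.2 CPM in libraries 1, 5 and 7, and at 0.654 CPM or less in the other four. Notum, a secreted Wnt inhibitor, was at 20.2, 20.2 and 21.6 CPM in libraries 1, 5 and 7, 6.18 in library 4, 2.93 in library 6 and at most 0.145 in libraries 2 and 3. Other members of the Wnt list went another way. Cdx1 was at 42.5 CPM in library 1 and at most 1.90 elsewhere, and Lgr5 was at 0.0278, 3.01 and 41.6 CPM in libraries 1, 5 and 7 and 49.1 in library 6. Ccnd1, a cyclin of the G1 phase, was at 135, 531 and 523 CPM in libraries 1, 5 and 7, 1257 in library 4 and 1070.5 in library 6, and the summed list was highest in library 4 (1289 CPM). The immediate early gene Fos was at 7.24, 19.6 and 13.2 CPM in libraries 1, 5 and 7 and at 96.5 to 269 CPM in the other four. Egr1, a target of ERK signalling, was at 11.4, 20.3 and 8.46 CPM in libraries 1, 5 and 7 and at 140 to 191 CPM in the other four. Not all ERK targets had these ranges: Ier3 was at 6.30 CPM in library 1 and 77.5 to 109.7 in the other six. Libraries 1, 5 and 7 were listed together only after their values for these genes were seen, and the set was not tested as a group.

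Most cell cycle and interferon genes were highest in 1 library each, while Nrf2 targets were highest in 6 different libraries and hypoxia genes in 5. Of 20 S phase genes 18 were highest in library 1, with Mcm5, a subunit of the replicative helicase, at 242 CPM against 27.7 to 44.0 elsewhere. Of 20 G2 and M phase genes 19 were highest in library 1, and 17 were lowest in library 7. The p53 target Cdkn1a, a cell cycle inhibitor, ran from 226 CPM (library 1) to 1078 (library 7), and Cdkn2a, a senescence gene, from 27.2 (library 1) to 493 (library 6). The chemokine gene Ccl2 was at 0.00309 CPM, 1 UMI, in library 1 and at 41.0 to 249 CPM in the other six. All 11 interferon response genes that reached 5 CPM were highest in library 3, where Isg15 was at 167 CPM against 49.0 in library 2 and at most 7.89 elsewhere. Of 12 genes of the unfolded protein and integrated stress response 9 were highest in library 3, with Atf5 at 303 CPM, and 7 were lowest in library 5, with Trib3 at 1.89 CPM. The hypoxia gene Adm ran from 0.247 CPM (library 1) to 56.3 (library 2), and the Nrf2 target Nqo1 from 4.79 (library 3) to 93.8 (library 4). Among imprinted genes 9 of 15 were highest in library 2, with H19 at 551 CPM there and 0.136 in library 1. Xist, the RNA that silences an X chromosome, was at 1.13 CPM in library 1 and 372 to 725 in the other six. The Y-linked gene Eif2s3y was at 65.2 CPM in library 1 and had 0 UMIs in the other six.

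**Figure D3:**
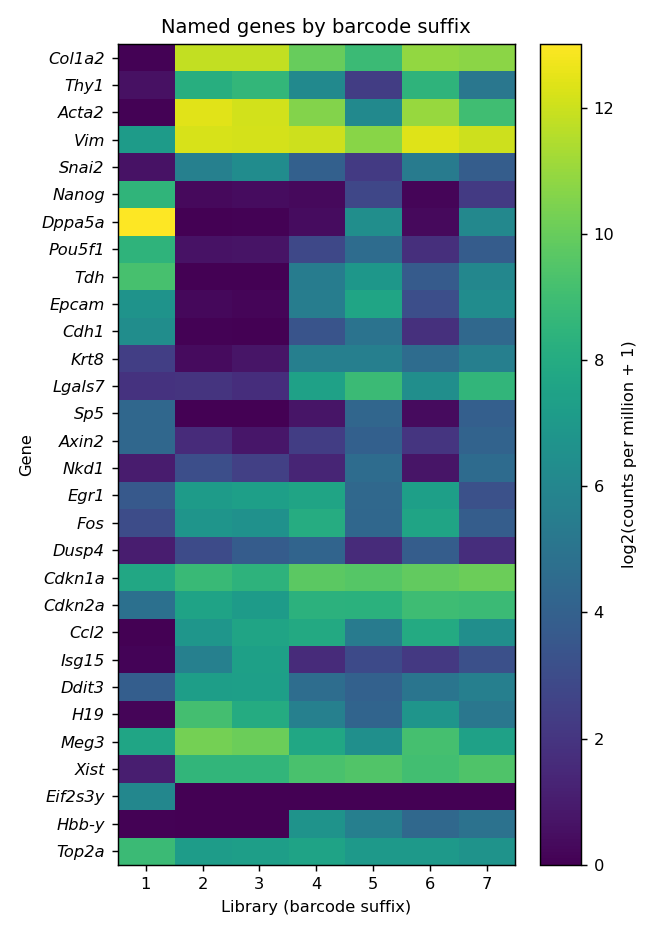
Level of 30 genes (rows) in each library (columns, barcode suffix), as log2 of CPM plus 1 (colour scale). Each cell is a sum over the kept cells of 1 library; Xist ran from 1.13 CPM in library 1 to 725 in library 5, and Hbb-y had 0 UMIs in libraries 2 and 3.

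Pluripotent-like cells were then set against fibroblast- or myofibroblast-like cells, as counts summed over all libraries. 99.6% of the pluripotent-like cells were from library 1, which held none of the other class. Of the 18689 fibroblast- or myofibroblast-like cells, 7430 were from library 2 and 7745 from library 3. The class and the library cannot be told apart in these values. Of 10641 genes at 5 CPM or more, 2262 were at least 2-fold higher and 2907 at least 2-fold lower in pluripotent-like cells, with a median log2 ratio of −0.05. DNA replication and division genes were higher: the median log2 ratio was 1.73 for the S phase list (18 of 20 higher) and 1.37 for the G2 and M phase list (20 of 20 higher), both at percentile 100 among random lists. Mcm5 was at 242 against 26.8 CPM (log2 ratio 3.12), and Cenpf, a kinetochore protein, at 343 against 85.5 CPM (1.99, counting interval 1.97 to 2.00). The clock list was lower, with a median of −0.83 and 16 of 18 members lower, at percentile 7.87. Cry1 was 1 of the 2 higher members, at 15.1 against 10.9 CPM (0.43, 0.38 to 0.48), and Rora was at 0.922 against 20.1 CPM (−3.45, −3.54 to −3.37). The p53 target list had a median of −0.93 with 13 of 15 members lower, at percentile 1.82. Cdkn1a was at 226 against 539 CPM, the death receptor Fas at 0.151 against 14.96 CPM, and Bax, a death effector, at 600 against 578 CPM. Without library 1, which left 49 pluripotent-like cells, the p53 median was −1.60.

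The other lists had medians on either side of 0. Some lists share members and are not separate results. Uhrf1 (log2 ratio 3.09), also an S phase member, set the median of the DNA methylation and TET list. Pgk1 (−0.13), also a glycolysis member, set that of the X chromosome list. Dnmt3b is in both the primed list and the DNA methylation and TET list. The Y chromosome list had the highest median, 5.58, and stood for library 1 alone. Next were the reprogramming factors (4.84, with Sox2 at 385 against 0.629 CPM and Myc lower at 5.68 against 28.2 CPM) and the DNA methylation and TET list (3.09, 9 of 11 higher). In the latter Dnmt3l, a cofactor of de novo methylation, was at 93.9 against 1.18 CPM and the methylcytosine dioxygenase Tet1 at 182 against 4.44 CPM. The primed list was at 2.79 (3 of 4 higher), over the 4 of its 9 genes that reached 5 CPM. Among these, Pou3f1 and Eomes were at only 8.51 and 6.34 CPM, against 0.200 and 0.219 CPM. Fst went the other way, at 26.2 against 100.5 CPM. The primed median therefore stands for few genes and not for the summed level of the list. The Wnt target list was at 2.70 (6 of 9 higher), where the homeobox gene Cdx1 was at 42.6 against 0.0200 CPM and the receptor Lgr5 at 0.0338 against 33.1 CPM. Oxidative phosphorylation (0.58, percentile 92.6), glycolysis (0.41, percentile 82.6), Nrf2 targets (0.17, percentile 66.8), hypoxia (−0.11, percentile 50.05) and the X chromosome list (−0.13, percentile 38.0) lay nearer to 0. Lower were the unfolded protein (−1.04), ERK target (−1.91), immediate early (−2.34), imprinted (−2.64), interferon (−3.20), mesenchymal (−3.40) and senescence lists (−4.70). Examples are Atf5 at 9.24 against 280 CPM, Jun at 9.06 against 183 CPM, H19 at 0.154 against 349.5 CPM, Zeb2 at 0.227 against 73.0 CPM and the chemokine Cxcl12 at 0.0829 against 225 CPM. The heat shock gene Hspb1 went the other way within its list, at 1310 against 251 CPM. Over all kept cells the summed interferon list was at 281 and 723 CPM in libraries 2 and 3, which held most fibroblast-like cells. It was at 64.4, 196, 71.9 and 180 CPM in libraries 4 to 7, against 73.9 in library 1. The lower interferon median may therefore stand for libraries 2 and 3 and not for the class. Without library 1 the X chromosome and hypoxia medians were 0.71 and 0.19, and without library 3 the X chromosome median was 0.00316. With cluster 8 counted as fibroblast-like, the hypoxia and Nrf2 medians were 0.02 and −0.04.

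**Figure D4:**
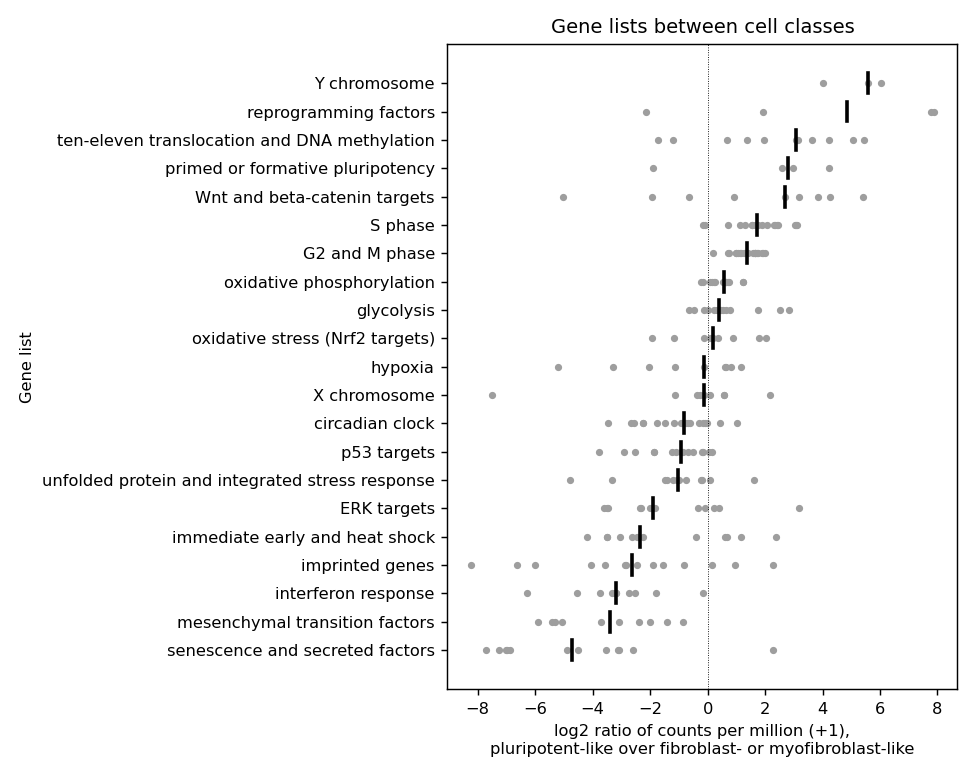
Log2 ratio of CPM plus 1 in pluripotent-like over fibroblast- or myofibroblast-like cells (x axis) for the members of each gene list (y axis). Grey points are genes, black bars are list medians, from −4.70 for senescence and secreted factors to 5.58 for the Y chromosome list; 99.6% of the pluripotent-like cells were from library 1.

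Within a library, pluripotent-like cells could be set against all other cells in library 5 (27 against 8570 cells) and library 7 (22 against 7654 cells). This comparison was added after the data were seen. Pou5f1 was at 539 against 21.1 CPM in library 5 and 476 against 10.7 CPM in library 7, and Tet1 at 173 against 7.83 and 211 against 5.58 CPM. The S phase list had medians of 1.69 and 1.78, and the G2 and M phase list 1.45 and 1.85. The clock list was lower in both, at −0.50 (counting interval −1.11 to −0.38) and −1.38 (−1.58 to −0.78). Cry1 itself was at 23.9 CPM (14.8 to 36.5) against 8.04 (7.67 to 8.43) in library 5, and at 21.9 (13.0 to 34.5) against 14.5 (13.97 to 15.1) in library 7, where the intervals overlapped. The p53 target list was at −1.02 and −2.12, with Cdkn1a at 204 against 756 CPM and 146 against 1083 CPM. The interferon list, lower in the pooled comparison, was at 0.66 (−0.17 to 1.09) and 1.35 (0.91 to 1.52) within these libraries. The unfolded protein list, also lower in the pooled comparison, was at 0.21 (0.00255 to 0.28) in library 5 and −0.08 (−0.19 to 0.18) in library 7. The median depth of the pluripotent-like cells was 34748 and 41771.5 UMIs, against 22622.5 and 20807 UMIs in the other cells.

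**Figure D5:**
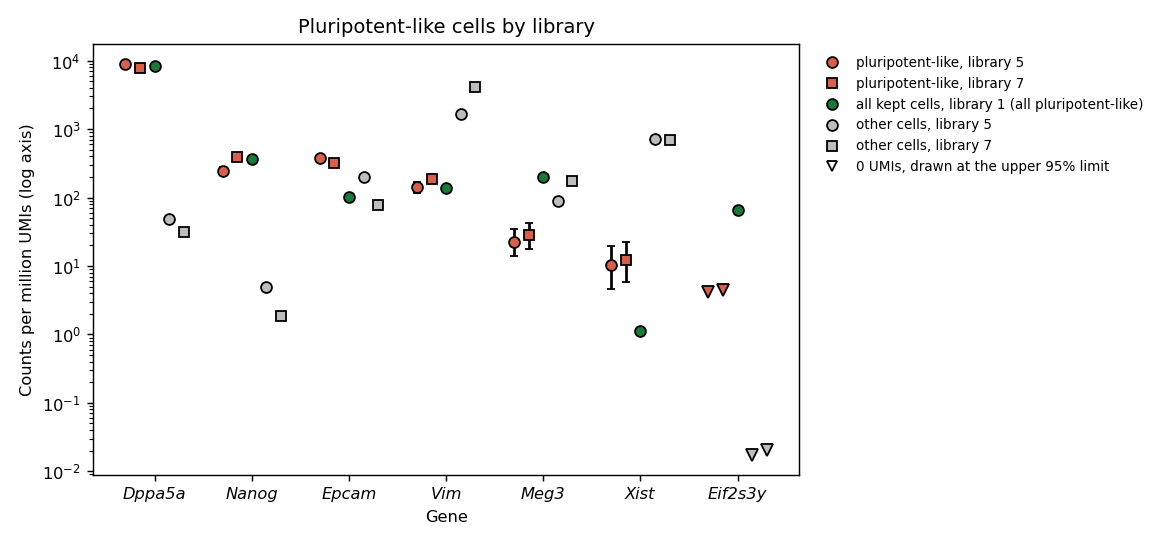
Level of 7 genes (x axis) in CPM (y axis, log scale) in pluripotent-like and other cells of libraries 5 and 7 and in library 1. Bars are 95% Poisson intervals for counting error, and triangles mark 0 UMIs at the upper limit; Xist was at 10.2 and 12.1 CPM in the pluripotent-like cells of libraries 5 and 7.

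Thinned to 5000 UMIs, a Cry1 UMI was found in 7.52%, 2.89%, 7.995%, 3.65%, 4.00%, 5.34% and 6.89% of the cells of libraries 1 to 7 (not thinned, 32.0%, 14.4%, 31.4%, 16.6%, 17.4%, 23.9% and 27.0%). Between 19 and 227 shallower cells per library were left out. Nanog, a core pluripotency factor, had a UMI in 82.6% of thinned cells of library 1, 1.23% of library 5 (1.011 to 1.49) and 0.646% of library 7 (0.478 to 0.853). In fibroblast-like cells, which should lack it, the share was 0.129% (0.0827 to 0.192), and libraries 2, 3, 4 and 6 had 0.0796%, 0.191%, 0.112% and 0.0127% (0.000322 to 0.0709 in library 6, below that class). Most fibroblast-like cells are themselves from libraries 2 and 3. Not thinned, the Nanog shares were 99.2%, 2.83%, 2.02% and 0.781% in library 1, library 5, library 7 and fibroblast-like cells. Median depths were 25363.5, 22640, 20828.5 and 24420 UMIs in the same order. An Epcam UMI was found in 36.6%, 9.83%, 31.9%, 2.40% and 15.1% of thinned cells of libraries 1, 4, 5, 6 and 7, against 0.161% of fibroblast-like cells (not thinned, 78.4%, 19.9%, 48.2%, 5.48% and 26.1%, against 0.899%). The order of libraries 1 and 5 in Epcam shares is opposite to that of their CPM and is not read as a difference.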

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

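The comparison within libraries 5 and 7, the count of cluster 8 as fibroblast- or myofibroblast-like and the removal of the 6% of cells with the highest doublet scores were added after the data were seen; the other settings were chosen before the data were examined. Planned averaging over libraries with 50 cells of both classes gave no value, because 0 libraries held both. No paired analysis was possible because each group held 1 sample and no suffix is tied to a sample. The cause of the changes below was not tested, except where a setting's construction shows it. Cry1 CPM in libraries 1 to 7 was 19.9, 7.84, 20.01, 9.12, 11.4, 14.7 and 19.8 on the scale without the 50 genes with most counts, and 22.2, 8.20, 21.0, 9.58, 13.0, 15.4 and 21.8 without mitochondrial and ribosomal protein genes, where a smaller total raises every value; the 7 values without a cell filter stayed within their counting intervals. The pooled share of pluripotent-like cells was 18.5% without a cell filter, and 0.104% to 23.7% when 1 library was left out, the lowest without library 1. For fibroblast- or myofibroblast-like cells it was 29.6% without a filter, 29.1% with the stricter filter, 29.9% with called doublets kept, 29.7% with 4000 variable genes and 37.6% with cluster 8 counted, and 21.5% (without library 3) to 39.8% (without library 1) with 1 library left out. For glia- or neural crest-like cells it was 0.151% at resolution 0.3 and 0.150% with 4000 variable genes, and 0.0726% to 0.241% with 1 library left out. For macrophage-like cells that range was 0.0683% to 0.251%. The unnamed share was 51.6% without a filter, 50.1% with the stricter filter, 49.4% with called doublets kept, 32.0% at resolution 1.0, 49.7% with 4000 variable genes and 41.7% without cluster 8, and 38.8% to 59.6% with 1 library left out. Without a filter, the depth rule left unnamed a cluster of 1609 cells with 7 pluripotency markers raised. It did the same for a cluster of 60 cells with 12 fibroblast or myofibroblast markers raised. The depth of these clusters was 0.0544 and 0.181 of their libraries' medians. The other 31 alternative shares, all of those with the 6% highest doublet scores left out among them, stayed within their binomial intervals. The median log2 ratio of the clock list was −0.76 without mitochondrial and ribosomal protein genes in the scale, −0.92 and −0.66 at pseudocounts of 0.1 and 5, −0.76 without a filter on low genes, −0.92 with the stricter cell filter, −0.91 with cluster 8 counted, and −0.50 and −1.38 within libraries 5 and 7. For p53 targets it was −0.83 on that scale, −0.81 at pseudocount 5, −0.85 with the stricter filter, −1.21 with cluster 8 counted, and −1.02 and −2.12 within libraries 5 and 7. For the S phase list it was 1.76 and 1.85 on the scales without the top 50 genes and without mitochondrial and ribosomal protein genes, 1.78 and 1.67 at pseudocounts of 0.1 and 5, 1.69 with the stricter filter, 1.71 with cluster 8 counted, and 1.69 and 1.78 within libraries 5 and 7. For the G2 and M phase list the values at these settings, cluster 8 aside, were 1.39, 1.48, 1.39, 1.28, 1.29, 1.45 and 1.85. With 1 library left out the clock median ran from −0.95 to −0.68, p53 from −1.60 to −0.79, S phase from 1.63 to 1.88, and G2 and M phase from 1.29 to 1.56. All 4 kept their sign in every setting run. Of the 21 lists with a value, some of which share members, 11 had a median below 0, 9 to 11 with 1 library left out, and 7 of 20 within library 5. The sign turned in 13 values of other lists. Values within libraries 5 and 7 are against all other cells, so a turn there is in a different comparison. Of those other cells 78 of 8570 and 1319 of 7654 were fibroblast- or myofibroblast-like. The interferon list held 5 and 7 members there, against 11 in the pooled comparison. For the X chromosome list these were 0.71 without library 1 and 0.00316 without library 3, in a range from −0.19 with 1 library left out, and 0.088 and 0.86 within libraries 5 and 7. For hypoxia they were 0.19 without library 1, in a range from −0.15, 0.017 with cluster 8 counted, and 0.52 and 0.00179 within libraries 5 and 7. For the interferon list they were 0.66 and 1.35 within libraries 5 and 7, for the unfolded protein list 0.21 within library 5, and for Nrf2 targets −0.32 within library 7 and −0.037 with cluster 8 counted. Of the list levels by library on other scales or without a cell filter, 564 moved beyond their counting intervals and 234 did not. Of the shares of cells with a UMI at 2000 UMIs or without thinning, 237 moved and 63 did not. Depth limits values of the 49 pluripotent-like cells outside library 1, which hold 879218 UMIs in library 5 and 823650 in library 7.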

Other observations

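The tests of Hbb-y for erythroid cells, and of the 49 pluripotent-like cells for carry-over, shared barcodes and doublets, were chosen only after the results were seen. The embryonic β-globin gene Hbb-y (chromosome 7, 103851749 to 103853216) was present in libraries 4, 5, 6 and 7, at 102, 47.8, 19.9 and 29.2 CPM, with a UMI in 36.9%, 17.4%, 9.30% and 10.1% of cells. Libraries 2 and 3 had 0 UMIs, and library 1 had 12. In library 4 the level was 123 CPM in cluster 4 (121 to 125) and 1.60 CPM in cluster 3 (0.585 to 3.47), and in library 7 it was 56.5 CPM in cluster 2 and 2.66 CPM in cluster 9.

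Hbb-y in libraries 4 to 7 was weighed against erythroid cells and free RNA. Erythroid cells carry several globins, but the other globins together reached at most 5.02% of the Hbb-y counts, in library 6. Free RNA would spread alike over clusters, but among clusters with at least 100 cells in library 4 the highest stood 77.4 times above the lowest, which rested on 6 UMIs. Both values argue against these explanations. A biological explanation was not tested, since no suffix is tied to a sample.

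The 49 pluripotent-like cells of libraries 5 (27 cells) and 7 (22 cells) clustered with the cells of library 1. Cells or reads carried over from library 1 would bring Y-linked transcripts, of which 219 UMIs were expected at the level of library 1 and 0 were found, which allows at most 1.69% of that level, and 0 of the 49 barcodes also occurred in library 1. Doublets with a mesenchymal cell would bring mesenchymal transcripts. Vim, Fn1, Tgfbr2 and Zeb2 together stood at 17.7% of the other cells in library 5 (15.7 to 19.8) and 8.55% in library 7 (7.64 to 9.54), below the bound set for doublets. The same sum was 366 CPM in the 49 cells, below the 437 CPM of library 1. A partner low in these genes would not be seen. In library 5, clusters 2 and 5, with Epcam and Krt8 raised, held 6193 and 1911 of 8597 cells. Epcam was at 352 CPM in the 49 cells, against 101 in library 1 and 145 in other cells of libraries 5 and 7. A mix at these average levels would not exceed both. An equal mix with such partners would also bring pluripotency transcripts well below library 1. Dppa5a, Sox2, Pou5f1 and Tdh were not lower, at 8331, 392, 509 and 775 CPM against 8269, 385, 350 and 588 in library 1. These values argue against equal mixes of library 1-like cells with such partners. Nanog, Zfp42 and Esrrb were lower, at 316, 112 and 59.3 against 366, 150 and 78.5 CPM. Doublets with a smaller share from a partner were left open. The higher UMI counts of the 49 cells, 34748 and 41771.5 at the median, remain unexplained. No biological explanation was tested.

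Cluster 11 (647 cells, counted as fibroblast- or myofibroblast-like) had contractile genes leading and few genes per cell, with medians of 1458 to 1986.5 against 4453.5 to 4937 in the other cells of 5 libraries. Lower depth does not account for this, since at 5000 UMIs its cells still had 60.5% to 68.7% of the genes of other cells. Cell fragments without a nucleus are a candidate explanation: the nuclear transcripts Malat1, Neat1, Meg3, Kcnq1ot1 and Xist together stood at 1.06% to 3.56% of their level in other cells. The mitochondrial share was 1.30% against 3.61% of other cells in library 7, and 3.42% to 4.73% against 3.37% to 4.32% in the other four. Whether such fragments arose in culture or in handling was not tested.

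A hypothesis of a different kind is that the 49 pluripotent-like cells have both X chromosomes active. Xist was at 10.2 CPM (4.68 to 19.4) in those of library 5 and 12.1 CPM (5.82 to 22.3) in those of library 7, against 728 and 693 CPM in the other cells. Relative to library 1, the median of 182 X-linked genes stood 0.53 log2 units (0.44 to 0.59) above that of 5267 autosomal genes, with 0.47 in library 5 and 0.60 in library 7. The interval came from resampling genes, not cells or counts. The interval crosses the bound set beforehand, so the test leaves the hypothesis open. The Xist-expressing other cells of libraries 5 and 7 gave 0.36 and 0.25 on the same measure, over 203 and 201 X-linked genes. These values were nearer to the pluripotent-like cells in library 5 than in library 7. Part of the shift may therefore come from library 1 as the reference, and the gene sets differed between the cells compared. Meg3, an imprinted RNA, was at 22.7 CPM (13.9 to 35.1) and 27.9 CPM (17.7 to 41.9) in these cells, against 203 CPM in library 1.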
